A study of Canis lupus familiaris with 8 samples.

How the data were processed

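Mammary tissue of female dogs was profiled on 1-colour expression arrays, 1 array per sample, with 4 arrays of tubulopapillary mammary tumor and 4 of control mammary tissue. Per the labels' protocols, tumor tissue was taken at surgery from 4 animals aged 2 to 4 years, from which the study collected 12 samples, 3 per animal. Control tissue came from animals euthanized for unrelated conditions. By the same protocols, all tissue was stored in an RNA preservative, and 400 ng of total RNA per sample was labelled with biotin. The kit they name is made for tailing and labelling short RNA. The probe sets named here are of mRNA genes, so that protocol may describe another array of the same study. The labels do not say which animal each tumor array came from, so 2 tumor arrays may share a dog, and the p-values then measure only the spread between these samples. Surgery and euthanasia follow the groups exactly.

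The deposited values are log2 expression per probe set. Per the submitters' processing notes they were made with RMA (robust multi-array average: background correction, normalization between arrays and a summary per probe set) in the Transcriptome Analysis Console. Versions, RMA options and the array's genome build are not given in the sources used here. The base of the logarithm is not stated either, and it was read as 2 because the values run from 1.48 to 12.6, the usual range of RMA. The values carry 2 decimals. No scanner files were used, so the background of each array is unknown and no probe set could be called above or below it. The number of arrays limits the precision.

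The table holds 27766 probe sets. GEO's annotation of the array lists 17167 of them: 16878 with 1 gene symbol, for 16295 genes, and 289 with several, which stay unnamed. The other 10599 are unnamed here, which does not mean that they lack a gene, and since they can include control probe sets the tests ran on the 17167 listed ones. That choice was made after the table was seen and before any call was known; testing all probe sets is an alternative. Through their gene identifiers, 16663 listed probe sets matched an entry in a RefSeq gene table of the assembly UU_Cfam_GSD_1.0, and each kept its symbol. Coordinates are not printed, because no build ties the array to that assembly. For gene lists, a gene is its probe set with the highest mean over all 8 arrays.

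Tumors were compared with controls in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2-sided moderated test, no covariates), with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. A second count asked in addition for a 2-fold difference of means. Before the data were examined, 40 gene lists of cell types, pathways and signs of tissue handling were fixed and tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Members were also adjusted over the list alone. The distance between arrays (1 minus Pearson's r) within tumors was compared with that within controls by an exact permutation test, 2-sided. With 4 arrays against 4 there are 70 labellings, and the smallest p an exact test can give is 0.0286.

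The genes named in the text follow a rule set before the data were examined. It takes genes past the threshold whose groups do not overlap, up to 12 per direction, and where fewer pass fills up to 5 with the smallest p, said not to pass. It adds up to 4 members per list with the smallest p, and ESR1, PGR, ERBB2, EGFR, BRCA1, MKI67, KRT5 and CDH1, whatever their values; the rest of that part of the rule is not reported here. Alternatives were a trended and robust prior, array weights, quantile normalization, median centring, leaving out dim probe sets, all probe sets, an ordinary Student test, an unadjusted threshold with a 2-fold difference, an estimated correlation, fry, averaging probe sets, Euclidean distance, and leaving out each array in turn.

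The fit was tested on simulated data with the fitted spread of each probe set. Noise was drawn independently between probe sets and with equal spread in both groups. The shares recovered and the false calls given next may therefore differ on the real arrays. Of 250 probe sets changed by 1 log2 unit it recovered 29.2%, and of 250 changed by 2 units 72.8%, over 17167 probe sets, with 6.9% of all calls false. In the list test on simulated data, each of the 40 lists was found when it was shifted by 1 unit. Other lists gave 8 false calls in all. That count does not give the error rate of the list test on the real arrays. There, other splits of the 8 arrays into groups of equal size called a median of 13 of the 40 lists. The estimated correlation between genes of a list reached 0.87, in oxidative phosphorylation, against the preset 0.01.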

Results

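Expression was measured in mammary tissue of female dogs on 8 arrays, 4 of tubulopapillary mammary tumors and 4 of control mammary tissue. Tubulopapillary tumors are epithelial growths that form tubules and papillae. All values are deposited log2 expression values, and array medians ran from 4.76 to 4.89. Control arrays resembled one another closely, with a mean Pearson correlation across probe sets of 0.959 over 6 pairs (0.943 to 0.975). Tumor arrays were less alike, at 0.824 over 6 pairs (0.714 to 0.907). They were on average no more like one another than like controls. The 16 pairs of a tumor with a control had a mean of 0.831 (0.680 to 0.958). Single arrays differed in this. Tumor replicate 4 had mean correlations of 0.942 with controls and 0.825 with other tumors, and replicate 1 of 0.864 and 0.859. Replicates 2 and 3 were nearer to other tumors (0.849 and 0.763) than to controls (0.826 and 0.692). Correlations across genes describe arrays, and genes are not independent replicates.

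The first principal component held 50.5% of the variance and the second 20.6%. On the first, tumor replicates 1, 2 and 3 scored -29.9, -56.6 and -111, whereas tumor replicate 4 scored 29.4, beside the controls at 39.4 to 45.5. Tumor replicate 3 stood apart from every other array. The SD of its values over probe sets was 1.24, against 1.69 to 1.78 on the other 3 tumor arrays and 1.72 to 1.77 on controls. Its median over 604 probe sets of olfactory receptors, genes with little expression outside the nose, was 2.86, against 2.45 to 2.56 elsewhere. The mean distance between tumor arrays exceeded that between control arrays by 0.136, a difference that did not pass the exact permutation test (2-sided p = 0.143). Permuted groups in that test mix tumors and controls. The difference between the groups then enters their distances, so the test does not measure spread alone. Without tumor replicate 3 the difference in mean distance was 0.0745, and without dim probe sets 0.272.

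**Figure D1:**
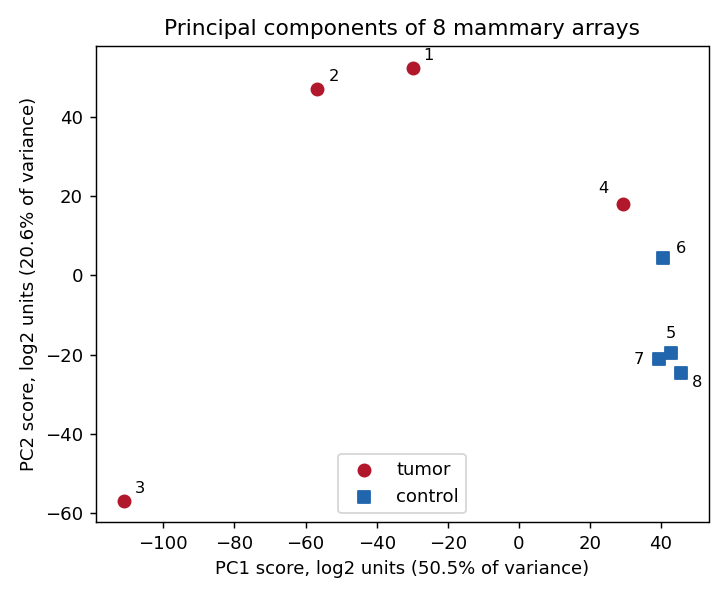
Scores of the 8 arrays on the first and second principal components, in log2 units, with 50.5% and 20.6% of the variance. Each point is 1 array, numbered by replicate, circles for tumors and squares for controls; tumor replicate 3 lies at -111 on the first component and tumor replicate 4 at 29.4, near the controls.

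The comparison of tumors with controls asks which genes differ between this tumor type and mammary tissue without it. The largest measured difference among the genes that passed was in MMRN1. It encodes a secreted protein of endothelium and platelets, abundant in lymphatic endothelium, and was 61.3-fold lower in tumors, at 3.59 ± 0.59 (SD, n = 4) against 9.53 ± 0.77 (SD, n = 4) in controls (adjusted p = 0.0055). PROX1, the transcription factor that specifies lymphatic endothelium, was at least 22.5-fold lower, at 2.85 ± 0.36 against 7.35 ± 1.00 (adjusted p = 0.0233). PKHD1L1, a large membrane protein, was at least 14.3-fold lower, at 3.07 ± 0.29 against 6.91 ± 0.92 (adjusted p = 0.0246), and all 4 of its probe sets lay lower in tumors, by -2.53 to -3.83. ABCA9, a lipid transporter of the ABCA family, fell by 4.45 (SE 0.47, adjusted p = 0.0233).

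The other genes that fell were the homeobox gene MEIS1 (-2.91 ± 0.28, log2 difference and SE), the Cdc42 activator DOCK11 (-2.35 ± 0.25), the transcriptional corepressor RUNX1T1 (-2.17 ± 0.22), and the peptidase NAALAD2, at least 3.30-fold lower at 3.49 ± 0.07 against 5.21 ± 0.30 (SD, n = 4). In PROX1, PKHD1L1 and NAALAD2 all 4 tumors lay below the 95th percentile of the olfactory receptor probe sets on their own array (3.86 to 5.11), a level not shown to exceed background, so these folds are minimums. In MMRN1, ABCA9 and RUNX1T1 3 tumors did, in MEIS1 2 and in DOCK11 1, and no control did in any of the 8, so those differences can be understated too. These 8 were the only probe sets to pass among 17167, each was at least 2-fold lower, and in each all 4 tumors lay below all 4 controls. No probe set rose with limma at adjusted p under 0.05. At an unadjusted p under 0.05 there were 1635 higher and 2150 lower, 3785 in all against 858 by chance if probe sets were independent. They are not: other splits of the 8 arrays into 4 and 4 gave a median of 255.5 and up to 2630. An unmoderated test per probe set called 0 in either direction after adjustment. Groups did not overlap in 2465 probe sets, 14.4% against an average of 2.86% by chance, from which a single split can likewise lie far.

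The count of calls rested on single arrays. Without tumor replicate 4 it was 1021 higher and 1698 lower, without tumor replicate 3 it was 0, and array weights gave 1410 and 1406. Without tumor replicates 1 and 2 it was 1 and 2, and without control replicates 5, 6, 7 and 8 it was 1, 52, 3 and 1. A trended and robust prior gave 6 higher and 40 lower, and leaving out dim probe sets 5 and 43. MMRN1 passed in 13 of 15 settings, missing the threshold without tumor replicate 3 (adjusted p = 0.0541) and in the unmoderated test (0.133). The 7 other genes passed in 7 to 9 of 14 or 15 settings. The differences themselves moved little: over the settings MMRN1 ran from -6.31 to -5.73 and PROX1 from -4.99 to -4.28, and the latter's largest move from the value with all arrays weighted equally, 0.496, was the largest of the 8 genes.

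**Figure D2:**
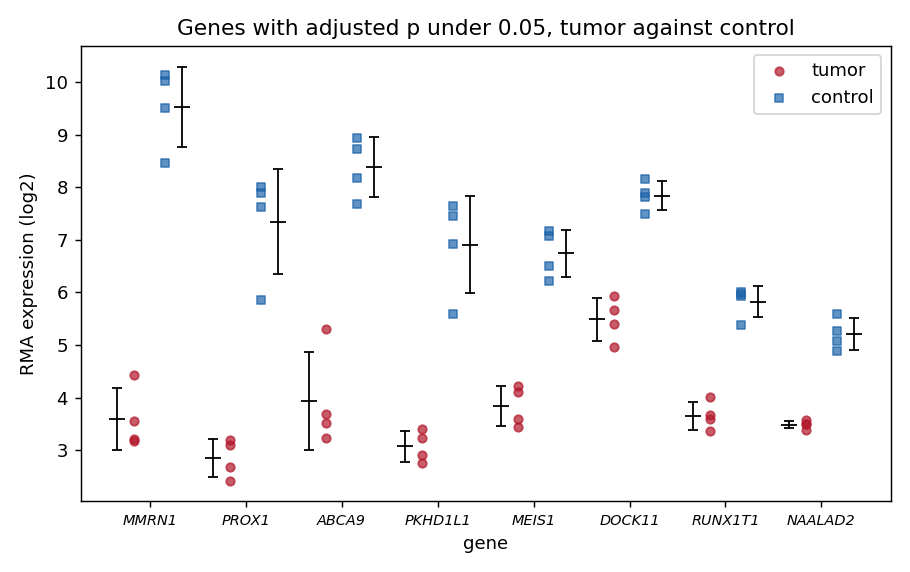
RMA expression on the log2 scale of the 8 genes past adjusted p = 0.05, 1 point per array, with the mean and SD of each group of 4 drawn beside the points. In each gene the 4 tumors (circles) lie below the 4 controls (squares); MMRN1 has means of 3.59 and 9.53.

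The 5 genes with the smallest p among those higher in tumors did not pass. S100A8, a calcium-binding protein of neutrophils and inflamed epithelium, was 5.22 log2 units higher (SE 0.78, adjusted p = 0.0620), at 8.76 ± 1.76 (SD, n = 4) in tumors and 3.54 ± 0.48 in controls. NGEF differed by 1.60 (adjusted p = 0.0557), SLC5A8, a monocarboxylate transporter, by 2.77 (0.0620), and RAB20 by 1.21 (0.0645). RASAL2, a Ras GTPase-activating protein, differed by 1.89 (0.0567), but its second probe set lay lower by -1.51. In all 5 the 4 tumors lay above the 4 controls for the probe set given, and all 5 passed with array weights and without tumor replicate 4.

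Genes used to classify mammary tumors did not pass either with all 8 arrays weighted equally. The estrogen receptor gene ESR1 was at 4.84 ± 0.87 (SD, n = 4) in tumors and 6.35 ± 0.80 in controls (adjusted p = 0.156), and the progesterone receptor gene PGR at 3.40 ± 0.94 and 5.61 ± 0.67 (adjusted p = 0.108), with all 4 tumors below all 4 controls. ERBB2 differed by 0.29, EGFR by -0.33, BRCA1 by -0.15 and CDH1, the epithelial cadherin, by -1.13, with adjusted p of 0.475, 0.665, 0.694 and 0.348. Single arrays moved these values: without tumor replicate 3 CDH1 was at -0.43 and EGFR at -0.0067. Without tumor replicate 4 EGFR was at -0.77 and ERBB2 at 0.17. MKI67, a marker of cycling cells, differed by -0.63 (adjusted p = 0.321). KRT5, a keratin of basal epithelium, differed by 2.54 (adjusted p = 0.119), with all 4 tumors above all 4 controls. Without tumor replicate 4, ESR1 (adjusted p = 0.0240), PGR (0.00504) and KRT5 (0.0291) passed, and with array weights PGR (0.0225) and KRT5 (0.0338). In BRCA1 the sign turned with array weights and without control replicate 6. BRCA1 lay below the 95th percentile of the olfactory receptor probe sets on every array except control replicate 6. PGR did so in tumor replicates 1, 2 and 3, and ESR1, ERBB2 and EGFR in tumor replicate 3. Those values were not shown to exceed background, so BRCA1 in particular cannot be read as unchanged.

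Among the 40 gene lists fixed beforehand, 12 passed with the preset correlation, 6 lower and 6 higher, and all 12 calls were lost with an estimated correlation. No member of any list passed over all genes, so the counts of members below are those adjusted over the list alone, beside 0 over all genes. Other splits of the 8 arrays into 4 and 4 called lists as freely: 23 of 35 splits, the real one included, called at least 12.

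Vessel genes had the lowest p. Of 15 measured endothelial genes 13 lay lower, 9 fell when adjusted over the list alone, and the mean was -1.13 (adjusted p = 1.69e-05, and adjusted p = 0.80 with an estimated correlation). CDH5, the endothelial cadherin, was at 6.16 ± 0.37 (SD, n = 4) against 8.42 ± 0.54, and the adhesion molecule PECAM1 at 6.33 ± 1.12 against 9.18 ± 0.60. The differences of EMCN and ERG were -2.23 and -1.47. All 4 tumor means lay below all 4 control means in the exact permutation test (p = 0.0286, the smallest it can give).

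T and NK cell genes lay lower in 16 of 17, 3 falling when adjusted over the list alone: the chemokine CCL5 (-3.43), the T cell receptor component CD3E (-2.39) and the granzyme GZMK (-1.96). The list passed at adjusted p = 1.95e-05 (adjusted p = 0.80 with an estimated correlation), with a mean of -1.26. Antigen presentation genes lay lower in 14 of 15, none passing when adjusted over the list alone, with B2M at -0.94, TAP1 at -1.15 and DLA-DQA1 at -2.07. That list passed at adjusted p = 1.82e-04 (adjusted p = 0.80 with an estimated correlation). Both lists varied among controls, from -0.93 to 1.30 for T and NK cells and from -0.81 to 0.82 for antigen presentation, each highest in control replicate 7.

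Growth factor receptor genes lay lower in 11 of 15, and 6 fell when adjusted over the list alone, among them ERBB4 (-2.87), IGF1R (-1.79), PDGFRB (-1.38) and the vascular receptor KDR (-1.28). Tumor replicate 4 had a list mean of -0.05, inside the controls (-0.09 to 0.25), against -1.18 to -0.82 in the other tumors. The list passed at adjusted p = 0.0151 (adjusted p = 0.80 with an estimated correlation). Fibroblast and collagen genes lay lower in 16 of 20, and adjusted over the list alone 6 fell and 1 was higher. Their array means overlapped (exact permutation p = 0.229): tumor replicate 4, at 0.11, lay above control replicates 7 (-0.98) and 8 (-0.48). The proteoglycan DCN differed by -2.35, PDGFRA by -2.44 and the fibroblast protease FAP by -2.07. The list passed at adjusted p = 0.0151 (adjusted p = 0.80 with an estimated correlation), but not without tumor replicate 3 (0.0938) or control replicate 5 (0.0653), nor with dim probe sets left out (0.162).

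Adipocyte genes lay lower in 15 of 17, none passing when adjusted over the list alone, and passed as a list at adjusted p = 0.0151 (adjusted p = 0.80 with an estimated correlation). ADIPOQ, the adipokine adiponectin, differed by -3.95 and the fatty acid carrier FABP4 by -2.76. The controls themselves ranged from -1.34 to 2.33 in the list mean, and the call ended without control replicate 8, the highest (adjusted p = 0.261), without tumor replicate 4 (0.117) and without dim probe sets (0.127).

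Proliferation genes formed 2 of the higher lists. DNA replication genes lay higher in 17 of 19, none passing when adjusted over the list alone, with E2F1 at 0.76, MCM5 at 0.81 and GINS1 at 0.85. The list passed at adjusted p = 0.0258 (adjusted p = 0.80 with an estimated correlation). Mitosis and proliferation genes lay higher in 20 of 24, none passing when adjusted over the list alone, with CDC20 at 1.08, CCNB2 at 1.00 and BIRC5 at 1.26. That list passed at adjusted p = 0.0440 (adjusted p = 0.91 with an estimated correlation). The mean of the mitosis list was 1.15 and 0.95 in tumor replicates 1 and 2, 0.04 and -0.17 in replicates 3 and 4, and 0.66 in control replicate 6. Both calls ended without tumor replicate 1 (0.186 for replication, 0.285 for mitosis), tumor replicate 2 (0.129 and 0.151) or control replicate 8 (0.0712 and 0.195). The mitosis call also ended without control replicate 5 (0.0914) or 7 (0.0509), with quantile normalization (0.116), with median centring (0.0503) and without dim probe sets (0.0635).

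Hypoxia and glycolysis genes, which share ENO1, LDHA and PGK1, lay higher in 15 of 16 and 13 of 14, none passing when adjusted over the list alone. The glucose transporter SLC2A1 differed by 2.22, the carbonic anhydrase CA9 by 1.83, the enolase ENO1 by 1.13 and the mutase PGAM1 by 1.25. Both lists passed at adjusted p = 0.0303 (adjusted p = 0.80 with an estimated correlation). The hypoxia mean was 1.89 in tumor replicate 2 and 0.10 to 0.45 in the others, and without that array the adjusted p was 0.260, and 0.197 for glycolysis. Leaving out control replicate 7 ended the hypoxia call (0.0519), and leaving out tumor replicate 4 the glycolysis call (0.0749).

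Neutrophil genes lay higher in 9 of 10, of which 2 rose when adjusted over the list alone, S100A8 and its partner S100A9 (4.03), both also made by inflamed squamous epithelium. S100A12 differed by 2.36 and the receptor gene CSF3R by 0.53. The list passed at adjusted p = 0.0480 (adjusted p = 0.80 with an estimated correlation). Its mean was 2.65 and 2.06 in tumor replicates 2 and 3, and 0.62 and 0.28 in replicates 1 and 4, where the list medians were -0.11 and -0.26. The mean of the skin keratinocyte list was also highest in replicates 2 and 3, at 2.27 and 1.41, against 0.39 and -0.19 in replicates 1 and 4. The call ended without tumor replicate 2 (0.151) or 3 (0.318) or control replicate 8 (0.0649), and with quantile normalization (0.100) or median centring (0.0503).

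Bone and cartilage genes lay higher in 11 of 12, none passing when adjusted over the list alone. The osteoblast factor SP7 differed by 0.78 and the cartilage collagen COL2A1 by 0.69, while RUNX2, a regulator of bone formation, differed by -1.14. The list passed at adjusted p = 0.0413 (adjusted p = 0.80 with an estimated correlation), and the call ended without tumor replicate 4 (0.0749), control replicate 8 (0.0649) or dim probe sets (0.162), and with quantile normalization (0.0583).

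**Figure D3:**
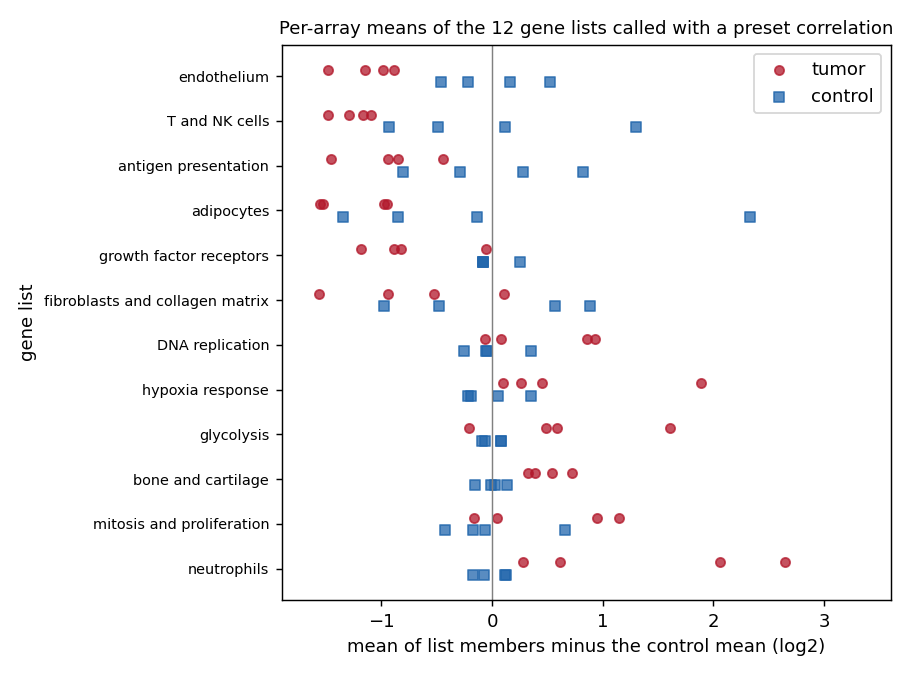
Mean of each called list's members in each array, as the log2 difference from the control mean, 1 point per array, circles for tumors and squares for controls. The 4 tumors lie below the 4 controls for endothelium and for T and NK cells; for hypoxia response tumor replicate 2 lies at 1.89, and for adipocytes control replicate 8 lies at 2.33.

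The other 28 lists did not pass, 12 with a higher and 16 with a lower direction, from adjusted p = 0.0754 upward. Skin keratinocyte genes and immediate early genes, a sign of tissue handling, both stood at 0.0754. The skin list passed without tumor replicate 1 (0.0310), tumor replicate 4 (0.0296) or control replicate 5 (0.0329), and the immediate early list without tumor replicate 1 (0.0140), tumor replicate 3 (0.0384) or control replicate 8 (0.00406). Without tumor replicate 3, oxidative phosphorylation (2.77e-04, and 0.0324 with quantile normalization of all 8 arrays), cytosolic ribosomal proteins (8.99e-04) and heat shock genes (0.0176) passed as higher. Basal and myoepithelial genes lay higher in 11 of 13 (adjusted p = 0.129), and 2 rose when adjusted over the list alone, the keratin genes KRT17 (2.40) and KRT5. The list passed without dim probe sets (0.0101) or control replicate 6 (0.0476). Without control replicate 6, interferon response (0.00779), mast cells (0.0371) and immune checkpoints (0.0446) passed as lower. Interferon response also passed without tumor replicate 4 (0.0296), mast cells without tumor replicate 3 (0.0457) and luminal epithelium, as higher, without tumor replicate 2 (0.0319). Skeletal muscle passed as higher without control replicate 7 (0.0410), where its direction with all arrays was lower. Hormone receptor and estrogen response genes lay lower in 9 of 14 (adjusted p = 0.139), and 3 fell when adjusted over the list alone, the chemokine gene CXCL12 (-3.46), the prolactin receptor gene PRLR (-3.87) and PGR. Genes of epithelial to mesenchymal transition stood at adjusted p = 0.129, and the 2 that fell when adjusted over the list alone were the transcription factors ZEB1 (-2.63) and ZEB2 (-2.56). In 3 of these lists, nerve and Schwann cells among them, the median, mean and test differed in sign.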

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

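The tests of tumor replicate 4 against a control label, by the share of probe sets beyond the controls, and of other splits for the gene lists were set before their results were seen; the other tests below were chosen after. Of 136 groups of 4 values examined, 10 held an array far from the other 3, where chance gives about 6.8 (1 in 20).

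Tumor replicate 3 was far from the other tumors in the SD of its values (1.24 against 1.69 to 1.78), in the olfactory receptor median (2.86 against 2.45 to 2.51), in the mean of the heat shock and unfolded protein list (-0.806 against 0.418 to 0.495) and in that of the skeletal muscle list (0.222 against -0.431 to -0.348). Tumor replicate 4 was far from the others in the interferon response list (0.318 against -1.03 to -0.912) and in PGR (4.80 against 2.75 to 3.09). Among controls, replicate 6 stood apart in the growth factor receptor list (0.248 against -0.0862 to -0.0802) and in NGEF (4.65 against 4.94 to 4.99). Control replicate 7 stood apart in the skeletal muscle list (1.85 against -0.790 to -0.420) and in RUNX1T1 (5.38 against 5.94 to 6.00).

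The 8 probe sets that passed, all of them at least 2-fold lower, were compared with the other ways to part the 8 arrays into 4 and 4. The real split was the only 1 of 35 to reach 8, with or without the 2-fold condition, and the highest other split gave 1. That is the smallest share this test can give. It was chosen after the count was known, and 2 tumor arrays may share a dog, so chance is made less likely but not excluded. For the gene lists chance may account for the count: 23 of the 35 splits called at least the 12 lists of the real one, and the highest other split called 21.

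The first pattern weighed is the low level of the lymphatic genes MMRN1, PROX1, PKHD1L1 and LYVE1, the last of which did not pass (-4.18, adjusted p = 0.0550). A loss of vessels of every kind may account for the pattern and stays open: 12 other lymphatic genes shifted by -0.93 on average, 0.199 from the endothelium mean and within the spread between tumors (SD 0.286, exact permutation p = 0.314; 0.210 and p = 0.371 for a narrower choice of 8). Those 12 differed widely, from -2.55 for RELN to 0.51 for FOXC2. They were not shown to be confined to lymphatic vessels, so their mean cannot part lymphatic from other vessels. The mean shift of the 4 genes, -4.61, was far below the endothelium mean of -1.13, but they were picked for their low values, so that gap decides nothing. Surgery against euthanasia cannot be told apart from tumor against control, with the handling list at adjusted p = 0.0754, and at 0.0140, 0.0384 and 0.00406 without tumor replicate 1, tumor replicate 3 and control replicate 8; a difference that belongs to the tumor stays open.

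The second pattern is that genes high in tumor replicate 2 alone were intermediate in tumor replicate 3. Of 31 probe sets at least 4 log2 units above the 6 remaining arrays in replicate 2, 100% were raised in replicate 3 by at least 1 unit, at a median ratio of -2.87 with an SD of 0.67; at 3 units it was 46 of 69, or 66.7%. RNA carried over from replicate 2 would keep a constant ratio, and the SD fell between the limits set for and against it, so carry-over stays open. Skin in both samples stays open too. In replicate 2 the epidermal keratins KRT1, KRT2 and KRT10 shifted by -2.22 relative to KRT4, KRT6A and KRT13, but KRT1 (4.36) exceeded KRT4 (3.69). In replicate 3 the epidermal keratins averaged 0.79 above the control mean and the other keratins 2.71. KRT2 was higher in tumor replicate 1 (5.88) than in replicates 2 and 3 (4.41 and 4.48). Squamous differentiation in both tumors, or samples of 1 dog, was not tested. Nor was the effect of the scale of replicate 3 on these ratios. Its values had an SD of 1.24, against 1.69 to 1.78 on the other arrays. The 95th percentile of its olfactory receptor probe sets was 5.11, against 3.86 to 4.01.

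The third pattern is that tumor replicate 4 lay near the controls, and that leaving it out raised the calls from 8 to 2719. A control sample under a tumor label is argued against: in probe sets called from the other arrays, replicate 4 lay beyond 3 controls on the tumor side in 59.8% to 63.6% and left-out controls in 26.9% to 42.8%, and 4-fold beyond them in 1.32%, 2.81%, 1.66% and 1.13%, against 0%, 0.684%, 0% and 0.0872% for control replicates 5 to 8 in the same probe sets. The limit set beforehand, 3 times the highest share of any control, could not be reached by the first of these shares, and the matched comparison was chosen in its place. Correlations of replicate 4 over all probe sets with controls, 0.930 to 0.958, overlapped those between controls, 0.943 to 0.975. Its mean with controls, 0.942, lay slightly below that of each control with the others (0.952 to 0.967). With tumor replicates 1, 2 and 3 it correlated at 0.9066, 0.8542 and 0.7144, where the highest control reached 0.8903, 0.8345 and 0.6995. Those gaps were small and were not tested, so the argument rests mainly on the displacements. Normal gland mixed into the sample stays open: the control-like share was 74.1% from genes lower in the other tumors (95% bootstrap interval over genes 72.2 to 76.2) and 89.1% from genes higher in them (87.7 to 90.6), 15.0 points apart, but the test takes the mean of 3 unlike tumors as the tumor's own profile, so the gap excludes nothing. A tumor close to normal gland may also explain the pattern and was not tested.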

How the results depend on the processing

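The exact test of list means and the Euclidean distance with group means removed were chosen after the data were seen. Quantile normalization and median centring each gave 9 lower and 0 higher probe sets, and all probe sets gave 12 and 0, within 1.5 times the main count. A trended and robust prior gave 6 higher and 40 lower (the same counts at 2-fold), array weights 1410 and 1406 (624 and 977 at 2-fold), leaving out dim probe sets 5 and 43 (the same at 2-fold), and the Student test 0 and 0. An unadjusted p under 0.05 with a 2-fold difference gave 363 and 1346. Leaving out 1 array gave 0 to 1021 higher and 0 to 1698 lower, or 0 to 493 and 0 to 1452 at 2-fold, both extremes set by tumor replicates 3 (0 lower) and 4. All 8 genes were among the calls with array weights, with the trended prior and without tumor replicate 4 or control replicate 6. The 7 genes other than MMRN1 passed in 7 to 9 of 14 or 15 settings, and in 2 or 3 of the 8 fits that left out an array. Array weights were 0.0919 for tumor replicate 3, 0.374 for tumor replicate 4 and 1.41 to 4.07 for controls. Tumor replicates 1 and 2 had 1.11 and 0.733, so every tumor array counted less than every control. The cause of the changed counts was not tested.

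Of the lists, 0 higher and 0 lower passed with an estimated correlation or with fry, whose lowest adjusted p were 0.805 and 0.162; fry's test for change in either direction called 9. An exact test of each list's mean, unadjusted, called 3 higher and 2 lower. Leaving out 1 array gave 2 to 9 higher and 5 to 9 lower, and 4 of the 12 lists passed without each array in turn (endothelium, T and NK cells, antigen presentation, growth factor receptors). The lowest count of higher lists, 2, came without tumor replicate 2, and without control replicate 8 it was 3. Without tumor replicate 3 the higher lists numbered 9, and without control replicate 6 the lower ones 9. Leaving out 1 array, the difference in distance between arrays ranged from 0.0745 without tumor replicate 3 to 0.170 without tumor replicate 1, and without dim probe sets it was 0.272 (exact permutation p = 0.114). With Euclidean distance it was 63.5, which did not pass as planned (exact permutation p = 0.0571) and passed after removing group means (0.0286). The difference was the same in both, so only the permuted splits changed. With group means left in, permuted groups mix tumors and controls, and the difference between the groups enters their distances. BRCA1 reversed to 0.0023 with array weights and 0.0033 without control replicate 6, and without control replicate 5 it was -0.25. That gene lay below the 95th percentile of the olfactory receptor probe sets on every array except control replicate 6. Among the alternatives for named genes, 236 values kept their direction and their side of the threshold, 49 kept the direction but no longer passed, 22 passed newly and 2 reversed. In the settings that change only the prior, the test or the set of probe sets, a direction cannot change. No paired analysis was possible because the groups share no replicate numbers. Without scanner files, signal over background could not be assessed.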

Other observations

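The genes in this part were chosen after their values were seen, as were the tests. Marker genes of several tissues differed between the controls. Of 15 skeletal muscle genes 9 were highest in control replicate 7, with TTN at 7.83 and NEB at 7.94 there against 2.98 to 3.63 for TTN in the other 7 arrays. Of 17 adipocyte genes 16 were highest in control replicate 8, the exception being CFD, lowest there at 4.74, with ADIPOQ at 11.2, PLIN1 at 7.98 and LEP at 7.88; ADIPOQ stood at 3.99 in control replicate 6. Of 9 milk protein and lactation genes 6 were highest in control replicate 6, with CSN2 at 10.1 and CSN3 at 11.2, and tumor replicate 4 carried CSN2 at 8.50 and CSN3 at 9.83, where tumor replicates 1, 2 and 3 had CSN2 at 2.94, 2.93 and 3.56.

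Squamous and cornified envelope genes, a list of 23 written after the data were seen with 21 measured, lay higher in tumors in all 21, 7 of them at an unadjusted p under 0.05. The list mean was 5.12 in tumor replicate 2 and 2.71 in replicate 3, but 0.58 and 0.41 in replicates 1 and 4. IVL, a cornified envelope protein, was at 10.5 and 8.20 in tumor replicates 2 and 3 and at 4.57 to 4.65 in the other 6 arrays. The desmosomal cadherin DSG1 was at 9.70 and 6.83 against 2.68 to 3.19, and the gap junction protein GJB6 at 10.6 and 7.75 against 2.70 to 3.28.

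Small leucine-rich proteoglycans, matrix proteins that bind collagen, lay lower in 7 of 11, with a mean of -1.13 that did not pass (exact permutation p = 0.0857) and with tumor replicate 4 at 0.13, inside the controls. The lowest members were OGN at -4.92 and OMD at -3.22. Relatives of ABCA9 also lay lower, ABCA5 by -0.98, ABCA6 by -2.81 and ABCA8 by -3.01, at adjusted p of 0.119, 0.135 and 0.0620. Among the unnamed probe sets, 4 passed when all were tested, each lower in tumors, and 3 of those hold identical values.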
